A study of Mus musculus with 12 samples.

How the data were processed

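RNA from colonic adenomas of 12 ApcMin mouse samples, taken at 150 to 160 days, was measured by RNA sequencing. Per the labels, RNA was extracted with TRIzol, libraries were made from 500 ng of total RNA with a TruSeq RNA kit, and single-end reads of 75 nt from an Illumina HiSeq instrument were aligned to the mouse genome mm10 with TopHat2. The processing notes name Cufflinks and Cuffdiff. The versions, the gene annotation, the library normalization and the handling of reads with several matches are not stated in the sources used here. The deposited values are in FPKM, fragments scaled to transcript length and to the number of mapped fragments, computed by the authors. The unit was read from the table's name, where it is spelled FPKKM, and from the tools named. The values are non-whole and their column totals differ, so the libraries were not scaled to a common total. No gene is at 0 in all 12 libraries, so such genes had been left out of the table.

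Groups were taken from the labels, and the table's column letters give each library's group. The columns are numbered 0 to 2 within a group and the labels number replicates 1 to 3, so a column was tied to its group but not to a single labelled replicate. Ensembl gene IDs were looked up in GENCODE M21, where 25119 of the 25705 IDs matched and 586 did not. Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested, 15150 in all, of which 13004 are protein-coding, 496 small RNAs and 321 pseudogenes. Values were analysed as log2(FPKM + 1) without further scaling.

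Differences were tested with limma 3.58.1 in R 4.3.3 by 1 model with 4 group means and no covariate, with a variance trend, and with 7 contrasts: each mutant group against the controls, each pair of mutant groups, and the mean of the mutant groups against the controls. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. The median standard error of a log2 difference was 0.262, and 0.214 for the pooled contrast. The prior degrees of freedom were 2.03. Gene lists with at least 4 tested members, 36 of the 38 written, were tested with camera (competitive, two-sided, preset correlation 0.01) and adjusted over the lists of a contrast. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move one way on balance, were run as alternatives. The lists, the model, the thresholds and the other settings to be tried were fixed before the data were examined.

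The rule for naming genes was fixed at the same time. It takes the largest rises and falls among called genes whose groups do not overlap (10 each for comparisons with the controls and between the groups that differ at 1 locus, 5 each otherwise), or, where fewer than 5 genes pass, the 10 with the smallest unadjusted p, said not to pass. It adds genes of DNA methylation and of the genotypes, and up to 4 members with the largest statistic from each list that passes. Gene models without a proper name are counted but not named, except that the few called ones were named after their values were seen. Names that stand for more than 1 gene ID were left out.

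Other settings, fixed beforehand, were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, scaling of all libraries to the same total, median-ratio scaling, quantile normalization, robust variance, library weights, only the groups of a comparison, and leaving out each library in turn. Chosen after seeing the data were protein-coding genes only, a term for libraries with Xist above 10 FPKM, and leaving out 2 or 3 libraries that stand apart. Other splits of the libraries were enumerated for the comparisons of 3 against 3 (10 splits) and drawn 100 times with a fixed seed for the pooled comparison. Shared calls were set beside 100 draws in which the residuals of the 12 libraries were permuted. Transcripts of Gm9855 and Gm15920 were compared with other transcripts by blastn 2.17.0.

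The tests were tried on simulated Tet1-null and control data built from these values. Of 50 genes altered at each size, limma called 16 (32%) at 2-fold, 27 (54%) at 4-fold, 33 (66%) at 8-fold and 40 (80%) at 16-fold, with 5 false calls and 0 calls in an unchanged comparison. A list shifted by 1 on the log2 scale passed and 0 others did. This does not give the rate of gene calls or false lists in the real data, where up to 23 lists passed in other splits. The relative depth of a library was read from the most common ratio to Tet1-null library 0 among genes under 0.3 FPKM in both, which 12.3 to 22.4% of these genes shared, and is a weak estimate. All columns of the table were used, and 0 pairs of libraries were identical.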

Results

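RNA abundance was measured in colonic adenomas of 12 mouse samples that carry the ApcMin allele, a truncating mutation of the tumour suppressor Apc that gives rise to intestinal adenomas. The samples form 4 groups of 3 libraries. The first group is Tet1-null, and the next is heterozygous for both a Tet1 mutation and the Tdg N151A allele (called double-heterozygous here). The others are heterozygous for Tdg N151A alone (Tdg-heterozygous) or wild type for Tet1 and Tdg (control). Tet1 encodes an enzyme that oxidises 5-methylcytosine, and Tdg encodes the glycosylase that removes the oxidised bases during active DNA demethylation. Libraries are named by their group and by the number, 0 to 2, of their column in the deposited table. The table lists 25705 genes, and the sum of FPKM per library ranged from 663551 to 977282, with a median of 736260. Between 13692 and 14384 genes per library reached 1 FPKM. The files hold no read counts, so the depth in reads is unknown. A relative depth, read from the most common ratio to Tet1-null library 0 among values below 0.3 FPKM, which only 12.3 to 22.4% of these genes shared, ranged from 0.755 in Tdg-heterozygous library 2 to 1.29 in control library 2. The p-values of single genes measure the spread between samples, and the labels do not say that each sample is a separate animal. Those of gene lists are described with the lists. Sex was not balanced: Xist, which is expressed in females, was above 10 FPKM in 1 of 3 Tet1-null, 0 of 3 double-heterozygous, 2 of 3 Tdg-heterozygous and 2 of 3 control libraries.

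Whole-gene FPKM does not verify the Tet1 genotypes. Tet1 was close to the floor in every library, between 0.127 FPKM (double-heterozygous library 0) and 0.621 FPKM (Tet1-null library 0), and 0 of the 12 libraries reached 1 FPKM, so Tet1 was not tested. The Tet1-null libraries had 0.621, 0.199 and 0.163 FPKM and the controls 0.403, 0.478 and 0.422 FPKM of Tet1, so Tet1-null library 0 had the highest value of all 12 and the 2 others lay below every control. Tdg (ENSMUSG00000034674, mm10 chromosome 10, 82629828 to 82650799) had 33.5 ± 5.36 FPKM (SD, n = 3) in the Tet1-null group, 37.4 ± 2.41 FPKM in the double-heterozygous, 28.8 ± 2.65 FPKM in the Tdg-heterozygous and 34.2 ± 4.03 FPKM in the control group. Its largest log2 difference, 0.37 between the double-heterozygous and the Tdg-heterozygous group, did not pass (adjusted p = 1), although the libraries did not overlap (35.4 to 40.1 against 25.8 to 30.7 FPKM). In the same order of groups, mean FPKM ± SD were Apc 15.4 ± 0.994, 15.6 ± 3.97, 14.8 ± 4.02 and 13.8 ± 1.99, Tet2 5.88 ± 1.20, 5.84 ± 1.44, 5.41 ± 1.67 and 4.78 ± 0.256 and Tet3 16.4 ± 4.01, 16.5 ± 0.950, 13.2 ± 2.46 and 15.2 ± 1.42. The values of the glycosylase gene were Mbd4 2.74 ± 0.569, 3.04 ± 0.810, 2.45 ± 0.894 and 2.78 ± 0.627. For the methyltransferase genes and their cofactor they were Dnmt1 16.04 ± 2.66, 17.1 ± 3.65, 16.1 ± 0.866 and 19.5 ± 5.31, Dnmt3a 11.5 ± 4.16, 9.53 ± 1.28, 8.36 ± 1.53 and 11.2 ± 1.96, Dnmt3b 2.84 ± 1.66, 2.77 ± 0.303, 2.18 ± 0.895 and 3.19 ± 0.734 and Uhrf1 20.6 ± 2.38, 21.7 ± 6.29, 24.7 ± 1.72 and 27.2 ± 9.66. Of these genes and Tdg, 0 passed in any of the 7 comparisons, and every adjusted p was at least 0.999.

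Few genes passed an adjusted p of 0.05 in any comparison, and all of them are gene models without a proper name, so they fall outside the rule for named genes and were named after their values were seen. Gm9855 (ENSMUSG00000085666, chromosome 10, 42054113 to 42055306) and Gm15920 (ENSMUSG00000080893, chromosome 5, 130188395 to 130188796) are annotated as processed pseudogenes. Gm9855 had 6.96 to 8.07 FPKM in the 6 libraries that carry Tdg N151A and at most 0.0434 FPKM in the 6 others. Gm15920 had 9.31 to 12.7 FPKM in the carriers and at most 0.533 FPKM in the others. Gm22692 (ENSMUSG00000092796, chromosome 2, 165908051 to 165908175, annotated as a miRNA) was listed at 0 in the 3 controls and at 5.78 to 20.8 FPKM in the 9 mutant libraries. Gm25390 (ENSMUSG00000087966, chromosome 10, 91005741 to 91005843, annotated as an snRNA) had 45.7, 21.3 and 20.6 FPKM in the Tet1-null libraries and was listed at 0 in the 9 others. Gm25390 is 103 nt and Gm22692 125 nt long, close to the read length of 75 nt, and their values, multiplied by the relative depth and rounded to whole multiples of the smallest one, sum to 4 (Gm25390) and 12 (Gm22692) multiples.

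**Figure D1:**
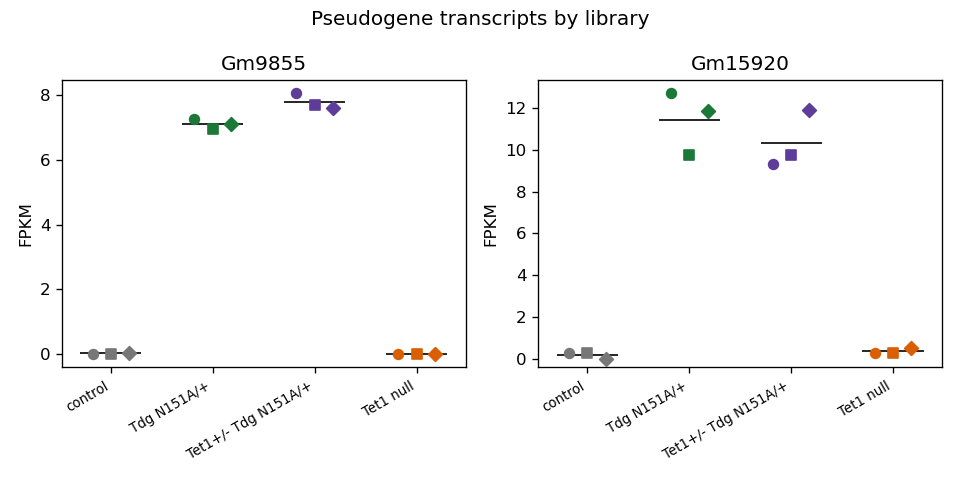
FPKM of the pseudogenes Gm9855 (left) and Gm15920 (right) in each of the 12 libraries by group, with points for libraries and lines for group means. Gm9855 has 6.96 to 8.07 FPKM and Gm15920 9.31 to 12.7 FPKM in the 6 libraries that carry Tdg N151A, against at most 0.0434 and 0.533 FPKM in the other 6.

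The gene lists tested were fixed before the data were examined, and a list's difference is its median log2 difference in log2(FPKM + 1). List calls are from camera with a preset correlation of 0.01, which takes a list's genes as nearly independent. Over the 10 lists that passed between Tet1-null and control samples, the estimated correlation was 0.247 to 0.897. Camera's p-values with the preset correlation therefore do not measure the spread between samples. With an estimated correlation 0 lists passed in each of the 7 comparisons, and fry also gave 0, so each list's adjusted p is followed by the one with the estimated correlation. Where leaving out 1 library ended a list's call, reversed the sign of its median or moved the median by more than 1.5 times, the median without that library follows. For every list that passed, the median, the mean and the test had the same sign. When p was adjusted over the list alone, 2 Paneth cell genes (Lyz1 and Defa21) passed between Tet1-null and control samples and 1 (Lyz1) between Tet1-null and double-heterozygous samples, against 0 over all genes tested, and 0 passed in any other list and comparison. Several lists followed single libraries. Wnt target genes had a mean score, against the control mean, of -3.02 in Tet1-null library 1, -1.93 in Tdg-heterozygous library 2 and -0.908 in double-heterozygous library 0, and between -0.135 and 0.291 in the 9 others. Neutrophil markers had 3.25 in Tdg-heterozygous library 2 and 2.56 in double-heterozygous library 0. Type I interferon genes had 2.54 in Tet1-null library 2 and -0.541 in Tet1-null library 1, and smooth muscle markers 2.10 in Tet1-null library 1.

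**Figure D2:**
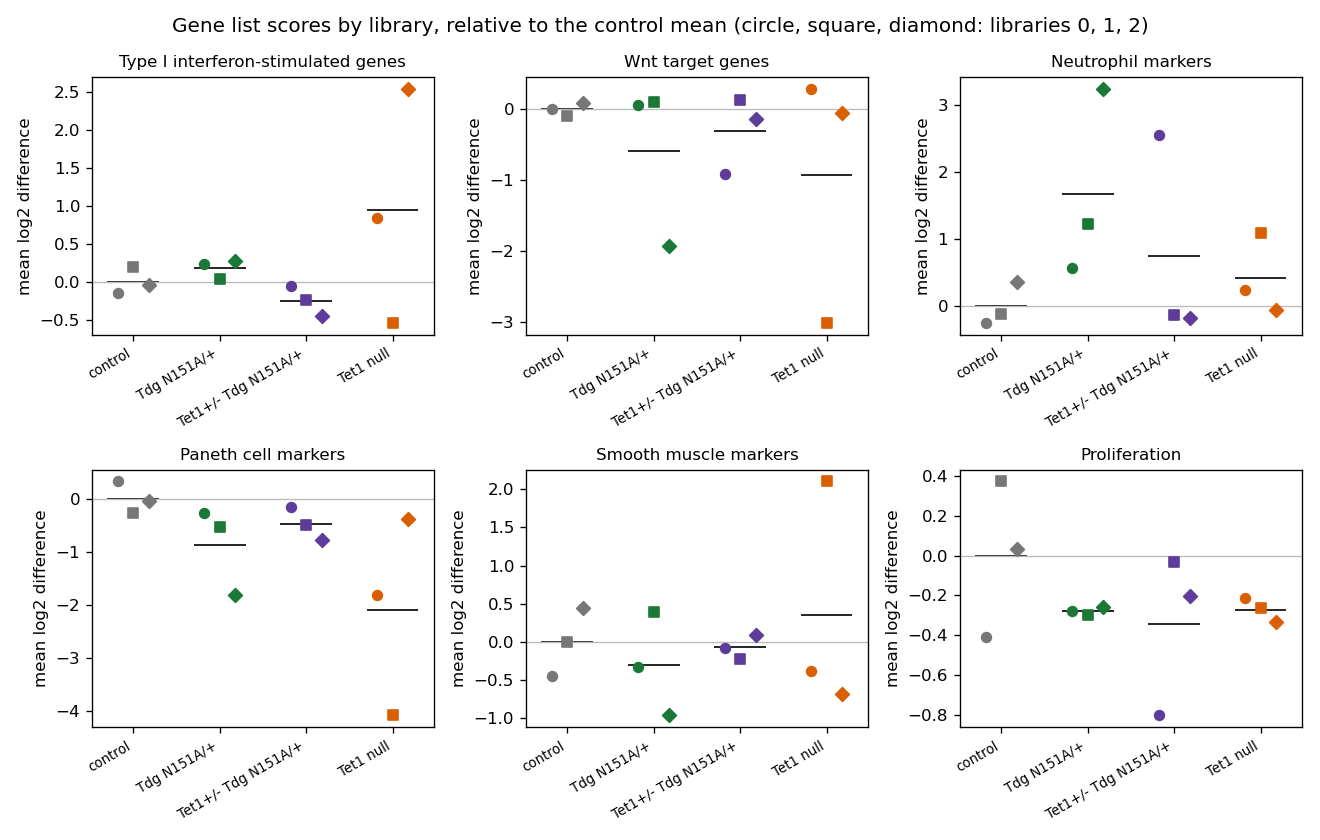
Mean log2 difference from the control mean of the members of 6 gene lists (vertical axes) in each library by group, where the circle, square and diamond are libraries 0, 1 and 2. Wnt target genes reach -3.02 in Tet1-null library 1, and neutrophil markers 3.25 in Tdg-heterozygous library 2.

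The comparison of Tet1-null with control samples asks what homozygous loss of Tet1 changes in ApcMin adenomas. Tet1-null samples had more RNA of the class I antigen-presentation genes H2-K1 (507 ± 287 against 225 ± 24.2 FPKM, log2 difference 1.02) and H2-D1 (481 ± 206 against 222 ± 23.6 FPKM, log2 difference 1.04). They had less RNA of the Paneth cell lysozyme gene Lyz1 (372 ± 355 against 1549 ± 266 FPKM, log2 difference -2.48) and the defensin gene Defa21 (6.99 ± 6.72 against 55.5 ± 8.22 FPKM, log2 difference -3.49). Of Wnt target genes, Myc had 37.3 ± 16.2 against 54.0 ± 2.77 FPKM, Mmp7 341 ± 307 against 649 ± 58.9 FPKM and the stem cell gene Lgr5 29.0 ± 34.3 against 44.1 ± 9.60 FPKM. None of these genes passed alone over all genes tested (adjusted p = 1). As lists, interferon-gamma and antigen-presentation genes were higher (28 of 29 higher, median 0.87, adjusted p = 5.13e-15, or 0.540 with estimated correlation). Their median was 1.52 without Tet1-null 1 and 0.43 without Tet1-null 2. Type I interferon genes were higher (26 of 27 higher, median 1.00, adjusted p = 3.14e-12, or 0.540 with estimated correlation). Their median was 0.17 without Tet1-null 2 (call lost) and 1.70 without Tet1-null 1. Examples are Irf7 (57.0 ± 63.4 against 13.5 ± 2.16 FPKM) and Xaf1 (35.8 ± 33.1 against 10.1 ± 1.61 FPKM). Paneth cell markers were lower (12 of 13 lower, median -1.88, adjusted p = 1.49e-13, or 0.486 with estimated correlation). Their median was -1.14 without Tet1-null 1 and -3.20 without Tet1-null 2. Wnt target genes were lower (25 of 26 lower, median -0.97, adjusted p = 1.66e-08, or 0.540 with estimated correlation). Their median was 0.21 without Tet1-null 1 (sign reversed) and -1.49 without Tet1-null 0. Intestinal stem cell markers, a list that shares Lgr5, Ephb3 and other members with the Wnt list, were lower (14 of 17 lower, median -0.53, adjusted p = 1.24e-05, or 0.540 with estimated correlation). Their median was -0.19 without Tet1-null 1 (call lost) and -0.89 without Tet1-null 2. Proliferation genes were lower, Pcna at 96.8 ± 3.86 against 126 ± 18.5 FPKM (25 of 25 lower, median -0.27, adjusted p = 2.22e-08, or 0.540 with estimated correlation). Their median was -0.056 without control 1 (call lost) and -0.48 without control 0. B and plasma cell markers such as Mzb1 (1.29) were higher (6 of 6 higher, median 0.62, adjusted p = 0.000105, or 0.540 with estimated correlation). Their median was 0.41 without Tet1-null 2. T and NK cell markers such as Klrd1 (0.92) were higher (5 of 6 higher, median 0.56, adjusted p = 0.02004, or 0.540 with estimated correlation). Their call was lost without Tet1-null 0 (median 0.33) or 2 (0.36) and without control 0 (0.26). Blood cell markers such as Hbb-bt (-1.40) were lower (7 of 7 lower, median -1.17, adjusted p = 0.000453, or 0.540 with estimated correlation). Their median was -0.43 without Tet1-null 2 (call lost), -0.45 without control 2 (call lost) and -1.76 without Tet1-null 1. Goblet cell markers such as Spink4 (-1.20) and Zg16 (-1.65) were lower (13 of 17 lower, median -0.57, adjusted p = 0.0342, or 0.899 with estimated correlation). Their median was 0.46 without Tet1-null 0 (sign reversed), -0.20 without control 0 (call lost), -1.64 without Tet1-null 1 and -1.07 without control 1. With library weights 18 lists passed instead of 10.

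At the level of single genes, 2 genes passed between Tet1-null and control samples, Gm25390 (log2 difference 4.82, SE 0.267, adjusted p = 8.40e-05) and Gm22692 (log2 difference 3.53, SE 0.376, adjusted p = 0.0209). Limma gave 247 genes an unadjusted p under 0.05, against 757.5 expected by chance. Without any 1 control library Gm22692 no longer passed (adjusted p = 0.111, 0.0739 and 0.173 without control 0, 1 and 2). The count of genes that passed was 4 without Tet1-null 0, 4 without Tet1-null 2 and 1 without control 2. It was 236 with library weights, where Tet1-null library 2 had a weight of 5.25, and 0 with protein-coding genes only or a mean of at least 5 FPKM. The groups did not overlap for 855 genes (5.64%), against 10% by chance. The named genes with the smallest p did not pass (adjusted p = 1). They include the immunoglobulin segments Ighv1-76 (2.87), Ighv1-81 (4.61), Ighv1-75 (1.19) and Igkv3-2 (3.00), the Paneth cell genes Lyz1 and Defa21, the non-classical class I gene H2-T22 (22.3 against 11.97 FPKM, 0.80), Upb1 (-1.18), Tor3a (0.50) and MIAT_exon5_1 (-2.93).

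Double-heterozygous and control samples differ in 1 allele of each gene, and also in sex, with Xist at most 0.237 FPKM in the double-heterozygous libraries and 298 and 361 FPKM in 2 of the 3 controls. In the double-heterozygous samples the cell division genes Ube2c (57.6 ± 15.0 against 84.7 ± 20.3 FPKM, log2 difference -0.56) and Bub1 (10.4 ± 4.45 against 16.4 ± 5.16 FPKM, log2 difference -0.64) were lower. The B cell receptor gene Cd79a (2.56 ± 2.38 against 0.574 ± 0.196 FPKM, log2 difference 0.99) and the coactivator gene Pou2af1 (2.27 ± 1.15 against 0.877 ± 0.317 FPKM, log2 difference 0.75) were higher, and none of these passed alone (adjusted p = 1). Proliferation genes were lower (25 of 25 lower, median -0.33, adjusted p = 2.82e-14, or 0.855 with estimated correlation). Their median was -0.12 without double-heterozygous 0, -0.50 without double-heterozygous 1, -0.55 without control 0 and -0.16 without control 1. B and plasma cell markers were higher (6 of 6 higher, median 0.66, adjusted p = 0.00143, or 0.855 with estimated correlation). Their median was 0.49 without double-heterozygous 2 (call lost) and 0.36 without control 2. Macrophage and monocyte markers such as Ms4a7 (-0.93) and Lyz2 (-1.17) were lower (12 of 18 lower, median -0.27, adjusted p = 0.0385, or 0.976 with estimated correlation). Their median was -0.35 without double-heterozygous 1 (call lost), -0.14 without double-heterozygous 2 (call lost), -0.087 without control 2 (call lost) and -0.47 without control 0. Type I interferon genes such as Isg15 (-0.86) and Bst2 (-0.77) were lower (21 of 27 lower, median -0.29, adjusted p = 0.0385, or 0.976 with estimated correlation). Their call was lost without double-heterozygous 1 (median -0.27) or 2 (-0.12) and without control 1 (-0.14). With a term for Xist, chosen after seeing the data and set by the other groups, the sign of this list reversed (median 0.34, adjusted p = 0.0520). Wnt target genes such as Myc (-0.47) were lower (23 of 26 lower, median -0.27, adjusted p = 0.0385, or 0.976 with estimated correlation). Their median was 0.052 without double-heterozygous 0 (sign reversed), -0.29 without control 0 (call lost) and -0.44 without double-heterozygous 1. The term for Xist also ended the calls of the Wnt list (median -0.19, adjusted p = 0.230) and the macrophage list (median -0.10, adjusted p = 0.373). It cannot tell sex from single libraries. The count of lists that passed was 5, and it was 10, 9 and 9 without double-heterozygous 0, double-heterozygous 2 and control 0, 11 with library weights and 1 with a mean of at least 5 FPKM.

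The 3 genes that passed between double-heterozygous and control samples were Gm9855 (log2 difference 3.11, SE 0.132, adjusted p = 6.33e-06), Gm15920 (log2 difference 3.27, SE 0.180, adjusted p = 3.96e-05) and Gm22692 (log2 difference 3.31, SE 0.376, adjusted p = 0.0254). Gm22692 no longer passed without any 1 library of either group (adjusted p = 0.113 to 0.196). The model with only these groups called 12 genes, and 0 passed among protein-coding genes only. The number of genes with an unadjusted p under 0.05 was 177, and 1180 genes (7.79%) did not overlap between the groups, against 10% by chance. The named genes that follow did not pass. Immunoglobulin segments led by p: Ighv9-1 (2.87, adjusted p = 0.212), Igkv3-12 (2.06), Igkv3-2 (4.16), Igkv4-79 (1.36) and Ighv1-80 (1.34). The protease gene Prss41 (1.66), the histidine ammonia-lyase gene Hal (1.05) and MIAT_exon5_1 (-2.87) came next, with the leukotriene A4 hydrolase gene Lta4h (63.7 ± 9.57 against 104 ± 10.9 FPKM, log2 difference -0.70).

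Tdg-heterozygous samples compared with controls address what 1 catalytic-mutant Tdg allele changes. The neutrophil markers Mmp8, a collagenase gene (10.2 ± 4.68 against 0.805 ± 0.0975 FPKM, log2 difference 2.54), Retnlg (182 ± 178 against 12.2 ± 4.08 FPKM) and S100a8 (1435 ± 1598 against 132 ± 21.6 FPKM) were higher. The mitotic kinase gene Plk1 was lower (24.6 ± 2.23 against 36.3 ± 9.48 FPKM), as was the methyltransferase gene Dnmt3b (2.18 ± 0.895 against 3.19 ± 0.734 FPKM). None passed alone (adjusted p = 1). Neutrophil markers were higher (17 of 17 higher, median 1.61, adjusted p = 7.94e-14, or 0.775 with estimated correlation). Their median was 0.59 without Tdg-heterozygous 2. Inflammatory genes such as Nos2 (1.32) and Il1a (1.61) were higher (27 of 31 higher, median 0.41, adjusted p = 0.000141, or 0.783 with estimated correlation). Their median was -0.083 without Tdg-heterozygous 2 (sign reversed), 0.24 without control 0 (call lost), 0.75 without Tdg-heterozygous 0, 0.85 without Tdg-heterozygous 1, 0.64 without control 1 and 0.82 without control 2. Hypoxia and glycolysis genes such as Vegfa (0.44) were higher (17 of 18 higher, median 0.34, adjusted p = 0.000468, or 0.783 with estimated correlation). Their median was -0.028 without Tdg-heterozygous 2 (sign reversed), 0.22 without control 1 (call lost), 0.59 without Tdg-heterozygous 0 and 0.53 without Tdg-heterozygous 1. Proliferation genes such as Plk1 were lower (25 of 25 lower, median -0.27, adjusted p = 1.20e-07, or 0.783 with estimated correlation). Their median was -0.11 without control 1 (call lost) and -0.51 without control 0. Interferon-gamma genes such as Gbp2 (1.13) were higher (24 of 29 higher, median 0.24, adjusted p = 0.00242, or 0.838 with estimated correlation). Their median was 0.49 without Tdg-heterozygous 2 and 0.47 without control 1. Their call was lost without Tdg-heterozygous 0 (0.13) or 1 (0.14) and without control 0 (0.034). Pan-epithelial markers such as Krt18 (0.42) were higher (16 of 17 higher, median 0.34, adjusted p = 0.00839, or 0.838 with estimated correlation). Their median was -0.20 without Tdg-heterozygous 2 (sign reversed), 0.26 without control 1 (call lost), 0.19 without control 2 (call lost), 0.58 without Tdg-heterozygous 0 and 0.61 without Tdg-heterozygous 1. Fetal-like and YAP target genes such as Msln (1.14) and Ly6a (1.18) were higher (11 of 16 higher, median 0.47, adjusted p = 0.0183, or 0.783 with estimated correlation). Their median was -0.059 without Tdg-heterozygous 2 (sign reversed), 0.39 without control 0 (call lost), 0.43 without control 1 (call lost) and 0.84 without Tdg-heterozygous 1. B and plasma cell markers such as Igj (1.07) were higher (6 of 6 higher, median 0.37, adjusted p = 0.00538, or 0.775 with estimated correlation). Their median was 0.59 without Tdg-heterozygous 2 and 0.57 without control 1. Their call was lost without Tdg-heterozygous 0 (0.39) or 1 (0.22) and without control 2 (0.21). Paneth cell markers such as Defa21 (-1.97) were lower (12 of 13 lower, median -0.88, adjusted p = 0.00250, or 0.783 with estimated correlation). Their median was -0.48 without Tdg-heterozygous 2 (call lost), -0.85 without control 0 (call lost) and -1.35 without Tdg-heterozygous 0. Wnt target genes such as Myc (-0.40) and Sox9 (-0.47) were lower (23 of 26 lower, median -0.59, adjusted p = 0.00839, or 0.846 with estimated correlation). Their median was 0.11 without Tdg-heterozygous 2 (sign reversed), -0.94 without Tdg-heterozygous 0 and -0.90 without Tdg-heterozygous 1. Intestinal stem cell markers such as Smoc2 (-0.89) were lower (13 of 17 lower, median -0.45, adjusted p = 0.0478, or 0.783 with estimated correlation). Their call was lost without Tdg-heterozygous 0 (median -0.60) or 2 (-0.030) and without control 0 (-0.41) or 1 (-0.33). DNA methylation genes such as Dnmt3b (-0.43) and Dnmt3a (-0.38) were lower (18 of 23 lower, median -0.16, adjusted p = 0.0365, or 0.783 with estimated correlation). Their median was -0.26 without control 0. Their call was lost without Tdg-heterozygous 0 (-0.16) or 2 (-0.099) and without control 1 (-0.088). With a term for Xist the calls of the stem cell list (adjusted p = 0.0512) and the DNA methylation list (adjusted p = 0.0532) were lost. With library weights 5 lists passed, and 15 in the model with only these groups. Of 36 lists, 12 passed with all libraries, 5 without Tdg-heterozygous 2 and 7 without control 1. Tdg-heterozygous 2 had mean list scores of 3.25 for neutrophil and -1.93 for Wnt target genes. It also had 1.32 for colonocyte, 0.975 for squamous epithelium and 1.07 for immediate-early and heat-shock genes (0.807 in double-heterozygous 0). The other 2 libraries of its group had 0.573 and 1.23 for neutrophil and 0.0633 and 0.108 for Wnt target genes.

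The 3 genes that passed between Tdg-heterozygous and control samples were the same gene models as for the double-heterozygous samples: Gm9855 (log2 difference 2.99, SE 0.132, adjusted p = 9.26e-06), Gm15920 (log2 difference 3.40, SE 0.180, adjusted p = 2.67e-05) and Gm22692 (log2 difference 3.07, SE 0.376, adjusted p = 0.0487). Leaving out any 1 library of the Tdg-heterozygous or control group ended the call of Gm22692 (adjusted p = 0.183 to 0.335). Among protein-coding genes only, 0 passed, and 6 genes passed in the model with only these groups. Limma gave 136 genes an unadjusted p under 0.05, and 608 genes (4.01%) did not overlap between the groups, against 10% by chance. Among the named genes, which did not pass (adjusted p = 1), Hal (1.19) and Lta4h (-0.76) moved as in the double-heterozygous samples. Hal is on chromosome 10, from 93488768 to 93519304, and Lta4h lies beside it, from 93453411 to 93484875. Others were the segments Igkv3-12 (2.11), Igkv4-79 (1.49), Ighv1-80 (1.43) and Ighv1-81 (3.87), and lower values for the centrosome gene Wdr62 (3.03 against 5.80 FPKM, -0.76), Scgb2b17 (-1.33), Upb1 (-1.13) and Cep85 (-1.83).

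By genotype, double-heterozygous and Tdg-heterozygous samples differ in 1 Tet1 allele on the same Tdg background. They also differ in sex, with Xist at most 0.237 FPKM in the former and 336 and 206 FPKM in 2 of the 3 latter libraries. With a term for Xist, chosen after seeing the data, 2 lists passed instead of 8, and of the 8 only neutrophil markers kept their call. Medians reversed for type I interferon (0.19), inflammatory (0.18) and proliferation genes (0.043). They were -0.085 for interferon-gamma genes, -0.19 for macrophage, -0.065 for T and NK cell markers and -0.035 for fetal-like genes. Adjusted p for these lists was 0.0644 to 0.906. Xist was low in every double-heterozygous library, so other groups set the term, including Tet1-null 2 (type I interferon score 2.54). The term cannot tell sex from single libraries. Values below are without this term. Lower in the double-heterozygous samples were the interferon-induced GTPase gene Gbp2 (4.91 ± 1.42 against 13.8 ± 7.09 FPKM, log2 difference -1.25), the nucleic acid sensor gene Zbp1 (8.90 ± 0.951 against 15.5 ± 1.29 FPKM, log2 difference -0.74) and the lactoferrin gene Ltf (2.13 ± 0.800 against 4.92 ± 2.11 FPKM, log2 difference -0.89). None passed alone (adjusted p = 1). Interferon-gamma genes such as Gbp2 and H2-K1 (-0.54) were lower (28 of 29 lower, median -0.41, adjusted p = 2.11e-07, or 0.973 with estimated correlation). Their median was -0.24 without double-heterozygous 0, -0.23 without Tdg-heterozygous 0, -0.24 without Tdg-heterozygous 1 and -0.73 without Tdg-heterozygous 2. Neutrophil markers such as Clec4d (-1.19), Clec4e (-1.31) and Ltf were lower (17 of 17 lower, median -0.89, adjusted p = 2.11e-07, or 0.973 with estimated correlation). Their median was -0.22 without Tdg-heterozygous 2 (call lost), -1.93 without double-heterozygous 0, -0.42 without double-heterozygous 2 and -1.37 without Tdg-heterozygous 0. Type I interferon genes such as Trim30a (-0.75), Zbp1 and Isg15 (-1.14) were lower (25 of 27 lower, median -0.38, adjusted p = 3.33e-05, or 0.973 with estimated correlation). Their median was -0.57 without double-heterozygous 0. Macrophage and monocyte markers such as Cd14 (-0.77) were lower (15 of 18 lower, median -0.30, adjusted p = 0.000186, or 0.973 with estimated correlation). Their median was -0.16 without double-heterozygous 2 and -0.18 without Tdg-heterozygous 0. Inflammatory genes such as Cxcl5 (-1.04) were lower (27 of 31 lower, median -0.31, adjusted p = 0.000514, or 0.973 with estimated correlation). Their median was 0.0079 without double-heterozygous 1 (sign reversed), 0.24 without Tdg-heterozygous 2 (sign reversed), -0.10 without double-heterozygous 2 (call lost), -0.88 without double-heterozygous 0, -0.53 without Tdg-heterozygous 0 and -0.54 without Tdg-heterozygous 1. T and NK cell markers such as Cd3g (-0.89) were lower (5 of 6 lower, median -0.36, adjusted p = 0.0117, or 0.973 with estimated correlation). Their median was -0.26 without double-heterozygous 0 (call lost) and -0.30 without Tdg-heterozygous 0 (call lost). Fetal-like and YAP target genes such as Ly6a (-0.68) were lower (13 of 16 lower, median -0.28, adjusted p = 0.0152, or 0.973 with estimated correlation). Their median was 0.061 without double-heterozygous 2 (sign reversed), 0.087 without Tdg-heterozygous 2 (sign reversed), -0.18 without double-heterozygous 1 (call lost), -0.78 without double-heterozygous 0, -0.50 without Tdg-heterozygous 0 and -0.57 without Tdg-heterozygous 1. Proliferation genes such as Mcm3 (-0.27) were lower, though Plk1 (0.38) was higher (18 of 25 lower, median -0.093, adjusted p = 0.0285, or 0.973 with estimated correlation). Their median was 0.16 without double-heterozygous 0 (sign reversed), -0.23 without double-heterozygous 1 and -0.17 without double-heterozygous 2. Their call was lost without Tdg-heterozygous 0 (-0.13), 1 (-0.15) or 2 (-0.028). Without double-heterozygous 0, 15 lists passed, and 5 passed without Tdg-heterozygous 2, against 8 with all libraries. Without the 3 libraries that stand apart (Tet1-null 1, Tdg-heterozygous 2 and double-heterozygous 0), a choice made after seeing the data, 12 passed.

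At the level of genes, limma called 0 between double-heterozygous and Tdg-heterozygous samples, with 231 genes at an unadjusted p under 0.05, and 848 genes (5.60%) did not overlap, against 10% by chance. Leaving out double-heterozygous 1 or Tdg-heterozygous 1 gave 1 call each, and leaving out the 3 libraries that stand apart gave 3. Gm9855 and Gm15920 had log2 differences of 0.12 and -0.13. The named genes with the smallest p (adjusted p = 1) were Ighv9-1 (2.04), Igkv3-2 (3.26), Wdr62 (0.81), Cdkl3 (0.79), Mettl22 (0.58), the Rac activator gene Tiam1 (11.7 against 7.17 FPKM, 0.64), the histone demethylase gene Kdm4b (0.66), higher in the double-heterozygous samples, and Ms4a4c (-0.85), lower in them.

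Tet1-null and Tdg-heterozygous samples were compared to ask whether the effects of the separate mutations differ. Tet1-null samples had more of the class II gene H2-Aa (130 ± 71.8 against 51.7 ± 18.3 FPKM, log2 difference 1.22), the smooth muscle actin gene Acta2 (89.5 ± 78.9 against 43.3 ± 24.2 FPKM, log2 difference 0.91) and the collagen gene Col1a2 (52.8 ± 26.0 against 22.9 ± 9.19 FPKM, log2 difference 1.14). They had less of the chemokine gene Cxcl3 (5.91 ± 1.41 against 120 ± 186 FPKM, log2 difference -2.56) and the cytokine gene Osm (2.16 ± 0.998 against 23.1 ± 35.6 FPKM, log2 difference -1.59). None passed alone (adjusted p = 1). In Tet1-null samples, type I interferon genes such as Stat2 (0.76) were higher (27 of 27 higher, median 0.82, adjusted p = 1.40e-09, or 0.570 with estimated correlation). Their median was -0.042 without Tet1-null 2 (sign reversed) and 1.499 without Tet1-null 1. Interferon-gamma genes such as H2-Aa were higher (27 of 29 higher, median 0.67, adjusted p = 3.37e-08, or 0.570 with estimated correlation). Their median was 0.13 without Tet1-null 2 (call lost), 0.42 without Tdg-heterozygous 2 (call lost) and 1.17 without Tet1-null 1. Smooth muscle markers such as Acta2 were higher (11 of 11 higher, median 0.65, adjusted p = 0.000171, or 0.570 with estimated correlation). Their median was 0.090 without Tet1-null 1 (call lost), 0.32 without Tdg-heterozygous 2 (call lost), 1.20 without Tet1-null 0, 1.28 without Tet1-null 2 and 1.12 without Tdg-heterozygous 1. Fibroblast and matrix markers such as Col1a2 were higher (18 of 22 higher, median 0.38, adjusted p = 0.00220, or 0.693 with estimated correlation). Their median was 0.099 without Tet1-null 1 (call lost), 0.26 without Tdg-heterozygous 2 (call lost) and 0.74 without Tet1-null 2. Neutrophil markers such as Mmp8 (-1.82) were lower (16 of 17 lower, median -1.18, adjusted p = 8.93e-10, or 0.570 with estimated correlation). Their median was -0.26 without Tdg-heterozygous 2. Inflammatory genes such as Cxcl3 (-2.56) were lower (28 of 31 lower, median -0.74, adjusted p = 1.25e-07, or 0.570 with estimated correlation). Their median was -0.16 without Tet1-null 1 (call lost) and -0.0074 without Tdg-heterozygous 2 (call lost). Cxcl3 is also in the neutrophil list. Paneth cell markers such as Defa24 (-2.75) were lower (13 of 13 lower, median -1.35, adjusted p = 3.96e-08, or 0.570 with estimated correlation). Their median was -0.28 without Tet1-null 1 (call lost) and -2.23 without Tet1-null 2. Blood cell markers such as Ppbp (-1.45) were lower (7 of 7 lower, median -1.24, adjusted p = 5.34e-06, or 0.570 with estimated correlation). Their median was -0.42 without Tet1-null 2 (call lost) and -0.58 without Tdg-heterozygous 2 (call lost). Fetal-like and YAP target genes such as Clu (-1.19) were lower (16 of 16 lower, median -0.44, adjusted p = 2.00e-05, or 0.570 with estimated correlation). Their median was -0.12 without Tdg-heterozygous 2 (call lost), -0.23 without Tet1-null 0, -0.73 without Tdg-heterozygous 0 and -0.88 without Tdg-heterozygous 1. Hypoxia and glycolysis genes such as Vegfa (-0.77) were lower (17 of 18 lower, median -0.28, adjusted p = 9.82e-05, or 0.570 with estimated correlation). Their median was 0.18 without Tdg-heterozygous 2 (sign reversed), -0.049 without Tet1-null 0, -0.42 without Tet1-null 1, -0.63 without Tdg-heterozygous 0 and -0.57 without Tdg-heterozygous 1. Wnt target genes such as Ephb3 (-0.58) were lower (20 of 26 lower, median -0.28, adjusted p = 0.000924, or 0.693 with estimated correlation). Their median was 0.79 without Tet1-null 1 (sign reversed), -0.022 without Tdg-heterozygous 0 (call lost), -0.046 without Tdg-heterozygous 1 (call lost), -0.95 without Tet1-null 0, -0.68 without Tet1-null 2 and -1.08 without Tdg-heterozygous 2. Mitochondrially encoded genes such as mt-Nd6 (-0.36) were lower (12 of 12 lower, median -0.15, adjusted p = 0.00141, or 0.661 with estimated correlation). Their median was 0.021 without Tet1-null 0 (sign reversed), 0.0034 without Tdg-heterozygous 2 (sign reversed), -0.071 without Tet1-null 2 (call lost), -0.41 without Tet1-null 1, -0.24 without Tdg-heterozygous 0 and -0.28 without Tdg-heterozygous 1. Epithelial antimicrobial genes such as Itln1 (-2.03) were lower (14 of 17 lower, median -0.57, adjusted p = 0.00270, or 0.570 with estimated correlation). Their median was 0.22 without Tet1-null 0 (sign reversed), -0.10 without Tdg-heterozygous 2 (call lost), -1.12 without Tet1-null 2 and -0.96 without Tdg-heterozygous 0. Intestinal stem cell markers such as Slc12a2 (-0.50) were lower (11 of 17 lower, median -0.091, adjusted p = 0.00902, or 0.570 with estimated correlation). Their median was 0.14 without Tet1-null 1 (sign reversed), -0.22 without Tet1-null 0 (call lost), -0.0036 without Tdg-heterozygous 0 (call lost), -0.063 without Tdg-heterozygous 1 (call lost), -0.46 without Tet1-null 2 and -0.46 without Tdg-heterozygous 2. Squamous epithelium markers such as Krt6a (-0.86) were lower (7 of 9 lower, median -0.21, adjusted p = 0.0294, or 0.570 with estimated correlation). Their median was -0.42 without Tdg-heterozygous 1. Their call was lost without Tet1-null 0 (-0.14), 1 (-0.20) or 2 (-0.18) and without Tdg-heterozygous 0 (-0.42) or 2 (-0.14). The term for Xist ended the calls of the stem cell and squamous lists, with medians of -0.13 (adjusted p = 0.0663) and -0.15 (adjusted p = 0.0709). Without Tdg-heterozygous 2, 6 lists passed instead of 15, and 12 passed with library weights.

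The genes that passed between Tet1-null and Tdg-heterozygous samples were Gm9855 (log2 difference -3.02, SE 0.132, adjusted p = 8.41e-06), Gm15920 (log2 difference -3.19, SE 0.180, adjusted p = 3.30e-05) and Gm25390 (log2 difference 4.82, SE 0.267, adjusted p = 3.30e-05). The count was 0 with protein-coding genes only and 8 without the 3 libraries that stand apart. Limma gave 168 genes an unadjusted p under 0.05, and 443 genes (2.92%) did not overlap, against 10% by chance. Named genes that did not pass (adjusted p = 1) were Ighv1-75 (1.67), the lipoprotein lipase gene Lpl (4.30 against 1.60 FPKM, 1.04), Asb2 (0.99), Fcho1 (0.78), Emc9 (0.67) and Coro7 (0.66), which were higher in Tet1-null samples, and Hal (-1.18), Igkv4-79 (-1.25), Prdm16 (-1.66) and Chi3l3 (-3.02), which were lower.

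Tet1-null and double-heterozygous samples differ in both genes. Tet1-null samples had more of the class I light chain gene B2m (1080 ± 810 against 274 ± 64.5 FPKM, log2 difference 1.60), the interferon-induced gene Bst2 (68.6 ± 60.0 against 15.8 ± 6.73 FPKM, log2 difference 1.65) and the T cell receptor gene Cd3g (5.06 ± 3.71 against 1.33 ± 0.954 FPKM, log2 difference 1.25). They had less of Lyz1 (372 ± 355 against 1481 ± 477 FPKM) and of Slc12a2 (103 ± 34.3 against 180 ± 26.6 FPKM, log2 difference -0.84). None passed alone over all genes (adjusted p = 1). Interferon-gamma genes were higher in Tet1-null samples (29 of 29 higher, median 1.14, adjusted p = 3.37e-26, or 0.267 with estimated correlation). Their median was 1.81 without Tet1-null 1 and 0.52 without Tet1-null 2. Type I interferon genes such as Bst2 were higher (27 of 27 higher, median 1.17, adjusted p = 5.26e-24, or 0.267 with estimated correlation). Their median was 1.82 without Tet1-null 1 and 0.34 without Tet1-null 2. T and NK cell markers such as Cd3g were higher (6 of 6 higher, median 0.75, adjusted p = 3.09e-05, or 0.267 with estimated correlation). Their median was 0.46 without Tet1-null 0. Macrophage and monocyte markers such as Ccr2 (0.80) were higher (18 of 18 higher, median 0.50, adjusted p = 1.75e-06, or 0.267 with estimated correlation). Their median was 0.25 without Tet1-null 0 (call lost) and 0.85 without Tet1-null 1. Smooth muscle markers such as Mylk (0.60) were higher (10 of 11 higher, median 0.48, adjusted p = 0.00878, or 0.940 with estimated correlation). Their median was -0.36 without Tet1-null 1 (sign reversed), 0.40 without double-heterozygous 1 (call lost), 0.84 without Tet1-null 0 and 1.02 without Tet1-null 2. Paneth cell markers were lower (12 of 13 lower, median -2.01, adjusted p = 2.07e-08, or 0.289 with estimated correlation). Their median was -0.63 without Tet1-null 1 and -3.05 without Tet1-null 2. Intestinal stem cell markers such as Slc12a2 were lower (17 of 17 lower, median -0.44, adjusted p = 0.000184, or 0.510 with estimated correlation). Their median was 0.020 without Tet1-null 1 (sign reversed), -0.76 without Tet1-null 2 and -0.29 without double-heterozygous 1. Wnt target genes such as Lgr5 (-1.51) were lower (25 of 26 lower, median -0.55, adjusted p = 0.00159, or 0.940 with estimated correlation). Their median was 0.45 without Tet1-null 1 (sign reversed), -0.33 without double-heterozygous 1 (call lost), -1.24 without Tet1-null 0 and -0.95 without double-heterozygous 0. Blood cell markers such as Hbb-bs (-1.35) were lower (7 of 7 lower, median -1.18, adjusted p = 0.000831, or 0.836 with estimated correlation). Their median was -0.44 without Tet1-null 2 (call lost), -0.59 without double-heterozygous 0 (call lost) and -1.78 without Tet1-null 1. Of 36 lists, 14, 14 and 15 passed without Tet1-null 2, double-heterozygous 0 and double-heterozygous 2, against 9 with all libraries, and 8 passed with a mean of at least 5 FPKM.

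The genes that passed between Tet1-null and double-heterozygous samples were again Gm9855 (log2 difference -3.14, SE 0.132, adjusted p = 5.77e-06), Gm15920 (log2 difference -3.06, SE 0.180, adjusted p = 5.01e-05) and Gm25390 (log2 difference 4.82, SE 0.267, adjusted p = 4.20e-05), and 5 passed without Tet1-null 0 or without Tet1-null 2. With library weights 82 genes passed, and with protein-coding genes only 0. Limma gave 275 genes an unadjusted p under 0.05, and 597 genes (3.94%) did not overlap, against 10% by chance. The named genes did not pass: Ighv9-1 (-2.48, adjusted p = 0.696), Lyz1 (-2.38), Vwa2 (-1.34), Prss41 (-1.37), Rpgrip1 (-1.23), Hal (-1.04) and Mpp3 (-0.90) were lower in Tet1-null samples, and Ighv1-76 (1.99), Ighv1-75 (1.66) and the heme-binding gene Hebp1 (0.87) were higher.

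The mean of the mutant groups, not each group, was compared with the controls. Proliferation genes such as Ube2c (-0.43) and Foxm1 (-0.41) were lower (25 of 25 lower, median -0.28, adjusted p = 1.23e-13, or 0.691 with estimated correlation). Their median was -0.48 without control 0 and -0.11 without control 1. Paneth cell markers such as Defa21 (-2.22) were lower (12 of 13 lower, median -1.08, adjusted p = 2.01e-07, or 0.649 with estimated correlation). Wnt target genes such as Myc (-0.50) and Sox9 (-0.43) were lower (24 of 26 lower, median -0.54, adjusted p = 1.91e-05, or 0.830 with estimated correlation). Their median was -0.32 without Tet1-null 1. Intestinal stem cell markers such as Smoc2 (-0.72) were lower (14 of 17 lower, median -0.38, adjusted p = 0.00585, or 0.830 with estimated correlation). Their median was -0.24 without control 1 (call lost), -0.22 without Tet1-null 1 and -0.20 without Tdg-heterozygous 2. Imprinted genes such as H19 (-0.63) and Rian (-0.74) were lower (12 of 17 lower, median -0.12, adjusted p = 0.0424, or 0.649 with estimated correlation). Their median was -0.18 without control 2. Their call was lost without Tet1-null 2 (-0.11), double-heterozygous 2 (-0.11), Tdg-heterozygous 2 (-0.15) or control 0 (-0.056). Neutrophil markers such as Mmp8 (1.64) were higher (16 of 17 higher, median 0.72, adjusted p = 2.92e-05, or 0.830 with estimated correlation). Their median was 0.47 without double-heterozygous 0. B and plasma cell markers such as Mzb1 (0.84) were higher (6 of 6 higher, median 0.58, adjusted p = 3.78e-05, or 0.649 with estimated correlation). Interferon-gamma genes such as H2-D1 (0.55) were higher (27 of 29 higher, median 0.28, adjusted p = 0.000338, or 0.967 with estimated correlation). Their median was 0.071 without control 0 (call lost), 0.48 without Tet1-null 1, 0.19 without Tet1-null 2, 0.43 without Tdg-heterozygous 2 and 0.56 without control 1. Type I interferon genes such as Oasl1 (0.80) were higher (23 of 27 higher, median 0.33, adjusted p = 0.0296, or 0.984 with estimated correlation). Their median was 0.054 without Tet1-null 2 (call lost), 0.34 without Tdg-heterozygous 0 (call lost), 0.26 without control 0 (call lost) and 0.58 without Tet1-null 1. With a term for Xist the stem cell list lost its call, with a median of -0.26 (adjusted p = 0.0625). Without control 2, 16 lists passed instead of 9, and with a pseudocount of 0.1 the count was 7.

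In the pooled comparison limma called 3 genes, Gm9855 (log2 difference 2.02, SE 0.108, adjusted p = 5.87e-05), Gm15920 (log2 difference 2.29, SE 0.147, adjusted p = 0.000173) and Gm22692 (log2 difference 3.30, SE 0.307, adjusted p = 0.00400). Gm22692 no longer passed without control 0 (adjusted p = 0.0546) or control 2 (adjusted p = 0.0568). The count of genes was 5 without Tet1-null 2, 5 without control 1 and 2 without control 0 or control 2. It was 0 with protein-coding genes only and 7 without the 3 libraries that stand apart. An unadjusted p under 0.05 was found for 156 genes, and 36 genes (0.238%) did not overlap, against 0.909% by chance. The named genes did not pass (adjusted p = 0.999). Lta4h (-0.62) and Upb1 (-1.03) were lower in all 9 mutant libraries than in the 3 controls, and Ighv1-81 (3.82) was higher in all 9. Igkv3-12 (1.77), Ighv1-80 (1.23) and Cep85 (-1.71) overlapped.

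The comparisons with the controls share the control libraries, so their log2 differences are related by construction. Across genes, which are not independent replicates, the correlation of the log2 differences was 0.527 for Tet1-null and double-heterozygous, 0.612 for Tet1-null and Tdg-heterozygous, and 0.566 for double-heterozygous and Tdg-heterozygous samples. Simulated unchanged groups with a shared control gave median correlations of 0.577, 0.528 and 0.526 over 100 draws. The covariances were 0.0956, 0.116 and 0.0961, against simulated medians of 0.140, 0.121 and 0.130. The shared calls numbered 1, 1 and 3, with a simulated median of 0 and highest values of 10, 3 and 1. Independent calls would give 0.000396, 0.000396 and 0.000594.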

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

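The tests of single explanations in this part were chosen after the result was seen, and the counts of other splits were planned. The results taken up here are the genes called between mutant groups, and also Gm22692 and the Wnt target list in Tet1-null samples. Between Tet1-null and Tdg-heterozygous samples these were Gm15920 (log2 difference -3.19), Gm9855 (-3.02) and Gm25390 (4.82). Between Tet1-null and double-heterozygous samples they were Gm15920 (-3.06), Gm9855 (-3.14) and Gm25390 (4.82). As 10 splits are too few for a share under 0.05, only the counts are given: the real split gave 3 genes and the highest other 6 in the first of these comparisons, and 3 and 3 in the second.

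Gm9855 and Gm15920 were higher in each of the 6 libraries that carry Tdg N151A than in every other library. A difference in depth is excluded, since the deepest library, control 2 (relative depth 1.29), had 0.0434 FPKM of Gm9855 and 0 of Gm15920. Both are processed pseudogenes with near-identical sequences elsewhere: Gm9855 matches Tdg at 99.2% over 1194 nt (9 mismatches) and, nearly as well, the genes Gm5597 (99.2% over 1193 nt, 10 mismatches) and Tdg-ps (98.9%, 13 mismatches), so its match does not single out Tdg, and Gm15920 matches Ndufa12 at 99.5% over 402 nt (2 mismatches). Tdg starts at 82629828 and Ndufa12 at 94198720, both on chromosome 10, so a candidate explanation is that the carriers hold a stretch of chromosome 10 around the Tdg allele whose sequence differs from the reference, and that reads of Tdg and Ndufa12 from it were placed on the pseudogene copies. Of 267 protein-coding genes within 20 Mb of Tdg, 2 (Hal and Lta4h) had an unadjusted p under 0.01 between carriers and the other libraries, against 8 of 12737 elsewhere (Fisher's exact test, two-sided, p = 0.0170). But Lta4h was also lower in the non-carrier Tet1-null libraries (64.3 to 93.7 FPKM) than in the controls (97.4 to 117 FPKM). Without it 1 of 266 genes remains (Fisher's exact p = 0.170). Hal and Lta4h had also been noticed on chromosome 10 before the window was chosen, so this test leaves the explanation open. A change in the transcription of both loci caused by the Tdg mutation cannot be told apart from this (6 of 6 carrier libraries above all others), because the allele and its surroundings are carried together. Reads, not analysed here, would decide it.

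Gm22692 and Gm25390 may rest on very few reads. Multiplied by the relative depth, their values above 0 lie within 0.147 of whole multiples of the smallest one, as 1 to 3 reads on a short feature would give. The nearest whole multiples sum to 4 for Gm25390 and 12 for Gm22692 over all libraries, so a biological difference in these RNAs was not tested.

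Wnt target genes were lower in Tet1-null samples (median -0.97), and the difference is consistent with the effect of a single library. Without Tet1-null library 1 the median was 0.21, and that library had a mean score of -3.02. The other 2 libraries had 0.291 and -0.0528, neither below the control range (-0.0949 to 0.0845). They show no fall with Tet1 loss, but 2 libraries cannot exclude one. Library 1 also had a smooth muscle score of 2.10, above the highest control (0.445), so a larger share of muscle wall or normal mucosa may have lowered the tumour's share there. Its colonocyte (1.58), goblet (1.43) and pan-epithelial (0.881) scores also lay above every control. Colonocyte and pan-epithelial scores were 1.32 and 1.30 in Tdg-heterozygous 2, and 0.481 and 0.680 in double-heterozygous 0, the other libraries with low Wnt scores. Against this, control 0 had a colonocyte score of 1.10 and a goblet score of 1.19 with a Wnt score of 0.0104. Muscle wall does not account for low Wnt scores in general: Tdg-heterozygous 2 (-1.93) and double-heterozygous 0 (-0.908) had smooth muscle scores of -0.962 and -0.0811. For Tet1-null library 1 it cannot be told apart from a difference between adenomas, since the evidence is 1 library.

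Other splits of the libraries were counted too. With 10 splits per comparison, too few for a share under 0.05, the real number of genes and the highest other were 2 and 2 for Tet1-null against control, 3 and 4 for double-heterozygous against control, 3 and 1 for Tdg-heterozygous against control, and 0 and 3 for double- against Tdg-heterozygous samples. For lists they were 10 and 19, 5 and 17, 12 and 14, and 8 and 14 in the same order, then 15 and 18 for Tet1-null against Tdg-heterozygous and 9 and 21 for Tet1-null against double-heterozygous samples. The number of these splits that gave as many genes, the real one included, was 2, 3, 1 and 10, and 4 and 2 for the comparisons between Tet1-null and the other mutant groups. For lists it was 9, 9, 7, 7, 4 and 9. In the pooled comparison chance is not excluded for genes (16 of 100 splits gave 3 or more, the highest other 19) or for lists (86 of 100 splits gave 9 or more, the highest other 23).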

How the results depend on the processing

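A comparison with the controls is named here by its mutant group alone, and pooled stands for the mean of the mutant groups. Robust variance was not run for lists, since it does not enter camera, and only the groups of a comparison changes nothing for the pooled one, so it was not run there. Gm9855 and Gm15920 kept their calls under every alternative that tested them. Protein-coding genes only tested neither, and a mean of at least 5 FPKM left out Gm9855. Gm22692 lost its calls against the controls in each single mutant group with a pseudocount of 5 and with the term for Xist. It also lost them with a mean of at least 5 FPKM (Tet1-null, Tdg-heterozygous), only the groups of the comparison (Tet1-null), no filter and robust variance (both Tdg-heterozygous), and in the pooled comparison with a pseudocount of 5. Gm25390 lost its calls with a mean of at least 5 FPKM and, against the controls, with only the groups of the comparison. Over the leave-outs the log2 differences of Gm9855 and Gm15920 were 3.09 to 3.12 and 3.15 to 3.33 (double-heterozygous) and 2.98 to 3.01 and 3.29 to 3.50 (Tdg-heterozygous). Of 152 alternative gene counts 103 stayed within 1.5 times, 15 were lower and 34 higher. Of 159 list counts 121 stayed, 23 were lower and 15 higher. Of 1534 list values 1138 kept the call and direction, 323 lost it and 73 reversed. Of 8632 values of named genes 36 lost and 31 gained a call. The 8565 others mostly had no call to lose, and 186 uncalled ones changed sign. Of 69 overlaps 35 stayed, 24 were lower and 10 higher. Scaling all libraries to the same total moved the median of all genes to -0.106 in Tdg-heterozygous samples and 0.116 between double- and Tdg-heterozygous samples, and with it, median-ratio scaling, quantile normalization and a pseudocount of 0.1 no list median reversed. The simulated 32% at 2-fold need not hold for these data.

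The replicate block fixed beforehand was fitted with the column number, 0 to 2, in place of the labelled replicate number, 1 to 3, a choice made after seeing the data, since a column cannot be tied to a labelled replicate. Libraries with the same number did not deviate together: the correlation of their deviations from the group means was over 0.1 in 4 of 18 same-numbered pairs, with a median of -0.0911, and 0 of the 12 libraries correlated best with their own number. So they share only a number. With this block, the numbers of genes called were 1 (Tet1-null), and the shared calls were 0 (Tet1-null and double-heterozygous, Tet1-null and Tdg-heterozygous). Under the block Gm22692 had an adjusted p of 0.109 (Tet1-null), 0.119 (double-heterozygous) and 0.202 (Tdg-heterozygous). The list calls that ended were stem cell and DNA methylation (Tdg-heterozygous) and imprinted (pooled), and the block ended no other call.

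The cause of the following changes was not tested unless said. With an estimated correlation and with fry, 0 lists passed in each of the 7 comparisons. With a pseudocount of 5, the numbers of genes called were 1 (Tet1-null), and the shared calls were 0 (Tet1-null and double-heterozygous, Tet1-null and Tdg-heterozygous). With no filter on low values, the numbers of genes called were 4 (Tet1-null) and 5 (double-heterozygous, Tet1-null against Tdg-heterozygous, Tet1-null against double-heterozygous, pooled), and the numbers of lists that passed were 3 (double-heterozygous), and the shared calls were 2 (Tet1-null and double-heterozygous). With a mean of at least 5 FPKM, the numbers of genes called were 0 (Tet1-null) and 1 (Tdg-heterozygous, Tet1-null against Tdg-heterozygous, Tet1-null against double-heterozygous), and the numbers of lists that passed were 1 (double-heterozygous), and the shared calls were 0 (Tet1-null and double-heterozygous, Tet1-null and Tdg-heterozygous) and 1 (double-heterozygous and Tdg-heterozygous). With robust variance, the shared calls were 0 (Tet1-null and Tdg-heterozygous). With only the groups of each comparison, the numbers of genes called were 1 (Tet1-null, double- against Tdg-heterozygous), 12 (double-heterozygous), 6 (Tdg-heterozygous, Tet1-null against Tdg-heterozygous) and 7 (Tet1-null against double-heterozygous), and the numbers of lists that passed were 8 (double-heterozygous). With library weights, the numbers of genes called were 236 (Tet1-null), 5 (double-heterozygous), 82 (Tet1-null against double-heterozygous) and 6 (pooled), and the numbers of lists that passed were 18 (Tet1-null), 11 (double-heterozygous) and 5 (Tdg-heterozygous), and the shared calls were 2 (Tet1-null and double-heterozygous). The medians that reversed with library weights were stem cell 0.040 (Tet1-null), inflammatory -0.041, pan-epithelial -0.050 (Tdg-heterozygous), proliferation 0.074 (double- against Tdg-heterozygous), inflammatory 0.13, fetal-like 0.062, smooth muscle -0.41, fibroblast -0.19, antimicrobial 0.87, stem cell 0.22 (Tet1-null against Tdg-heterozygous) and Paneth 0.019, stem cell 0.048, Wnt target 0.047, smooth muscle -0.41 (Tet1-null against double-heterozygous). The weight of Tet1-null library 2 was 5.25, against 0.457 and 0.256 for libraries 0 and 1, so these Tet1-null values rest mainly on 1 library.

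The next alternatives were chosen after seeing the data. With protein-coding genes only, the numbers of genes called were 0 (Tet1-null, double-heterozygous, Tdg-heterozygous, Tet1-null against Tdg-heterozygous, Tet1-null against double-heterozygous, pooled), and the shared calls were 0 (Tet1-null and double-heterozygous, Tet1-null and Tdg-heterozygous, double-heterozygous and Tdg-heterozygous). The called genes are not protein-coding, which is the cause. With a term for Xist, the numbers of genes called were 1 (Tet1-null), and the numbers of lists that passed were 2 (double- against Tdg-heterozygous), and the shared calls were 0 (Tet1-null and double-heterozygous, Tet1-null and Tdg-heterozygous). The medians that reversed with a term for Xist were type I interferon 0.34 (double-heterozygous) and type I interferon 0.19, inflammatory 0.18, proliferation 0.043 (double- against Tdg-heterozygous). The 2 libraries are Tet1-null 1 and Tdg-heterozygous 2, and the 3 libraries add double-heterozygous 0. Without the 2 libraries, the numbers of genes called were 4 (Tet1-null) and 5 (double-heterozygous, Tdg-heterozygous, Tet1-null against double-heterozygous, pooled), and the numbers of lists that passed were 8 (double-heterozygous), 6 (Tdg-heterozygous) and 14 (Tet1-null against double-heterozygous), and the shared calls were 2 (Tet1-null and double-heterozygous, Tet1-null and Tdg-heterozygous) and 5 (double-heterozygous and Tdg-heterozygous). The medians that reversed without the 2 libraries were Wnt target 0.21 (Tet1-null), inflammatory -0.083, hypoxia -0.028, Wnt target 0.11, pan-epithelial -0.20, fetal-like -0.059 (Tdg-heterozygous), inflammatory 0.24, fetal-like 0.087 (double- against Tdg-heterozygous), inflammatory 0.20, fetal-like 0.031, smooth muscle -0.47, Wnt target 0.062, fibroblast -0.056 (Tet1-null against Tdg-heterozygous) and stem cell 0.020, Wnt target 0.45, smooth muscle -0.36 (Tet1-null against double-heterozygous). Without the 3 libraries, the numbers of genes called were 8 (Tet1-null, Tet1-null against Tdg-heterozygous, Tet1-null against double-heterozygous), 9 (double-heterozygous), 6 (Tdg-heterozygous), 3 (double- against Tdg-heterozygous) and 7 (pooled), and the numbers of lists that passed were 11 (double-heterozygous) and 15 (pooled), and the shared calls were 4 (Tet1-null and double-heterozygous), 2 (Tet1-null and Tdg-heterozygous) and 5 (double-heterozygous and Tdg-heterozygous). The medians that reversed without the 3 libraries were Wnt target 0.21 (Tet1-null), Wnt target 0.052 (double-heterozygous), inflammatory -0.083, hypoxia -0.028, Wnt target 0.11, pan-epithelial -0.20, fetal-like -0.059 (Tdg-heterozygous), proliferation 0.17 (double- against Tdg-heterozygous), inflammatory 0.20, fetal-like 0.031, smooth muscle -0.47, Wnt target 0.062, fibroblast -0.056 (Tet1-null against Tdg-heterozygous), Wnt target 0.10, smooth muscle -0.41 (Tet1-null against double-heterozygous) and Wnt target 0.10 (pooled).

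Leaving out 1 library at a time gave numbers of genes called of 1 to 4 (Tet1-null), 0 to 1 (double- against Tdg-heterozygous), 3 to 5 (Tet1-null against double-heterozygous) and 2 to 5 (pooled). The numbers of lists that passed were 4 to 10 (double-heterozygous), 5 to 15 (Tdg-heterozygous), 5 to 15 (double- against Tdg-heterozygous), 6 to 18 (Tet1-null against Tdg-heterozygous), 12 to 15 (Tet1-null against double-heterozygous) and 8 to 16 (pooled). The shared calls were 0 to 2 (Tet1-null and double-heterozygous) and 0 to 3 (Tet1-null and Tdg-heterozygous). The list medians with a reversed sign ranged as follows: Wnt target -1.49 to 0.21, goblet -1.64 to 0.46 (Tet1-null), Wnt target -0.44 to 0.052 (double-heterozygous), inflammatory -0.083 to 0.85, hypoxia -0.028 to 0.59, Wnt target -0.94 to 0.11, pan-epithelial -0.20 to 0.61, fetal-like -0.059 to 0.84 (Tdg-heterozygous), inflammatory -0.88 to 0.24, fetal-like -0.78 to 0.087, proliferation -0.23 to 0.16 (double- against Tdg-heterozygous), type I interferon -0.042 to 1.499, hypoxia -0.63 to 0.18, Wnt target -1.08 to 0.79, mitochondrial -0.41 to 0.021, antimicrobial -1.12 to 0.22, stem cell -0.46 to 0.14 (Tet1-null against Tdg-heterozygous) and stem cell -0.76 to 0.020, Wnt target -1.24 to 0.45, smooth muscle -0.36 to 1.02 (Tet1-null against double-heterozygous). A group left with 2 libraries shares the spread of the other groups.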

Other observations

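The following values belong to no comparison of the groups. Xist, which is expressed in females, was at 206 to 361 FPKM in Tet1-null 2, Tdg-heterozygous 0 and 2, and control 1 and 2, and the Y-linked gene Ddx3y was at 15.5 to 22.0 FPKM in the 3 double-heterozygous libraries. The first principal component of the log2 values held 37.2% and the next 11.2% of the variance. On the first, Tdg-heterozygous 2 (80.8), Tet1-null 1 (78.9) and double-heterozygous 0 (42.5) stood apart from the 9 others (-58.6 to 3.31).

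Hal had 0.542 to 2.21 FPKM in the 6 carriers of Tdg N151A and at most 0.149 FPKM in the others, and the neighbouring gene Lta4h had 53.6 to 73.1 FPKM in the carriers and 64.3 to 117 FPKM in the others. Between carriers and the others, a contrast chosen after seeing the data, the log2 difference was 1.12 for Hal (adjusted p = 0.288) and -0.53 for Lta4h (adjusted p = 1). Lists that did not pass between Tet1-null and control samples include DNA methylation genes (17 of 23 lower, adjusted p = 0.0807), imprinted genes (adjusted p = 0.1002) and genes reported methylated in colorectal tumours with a CpG island methylator phenotype (14 of 21 lower, median -0.21, adjusted p = 0.120).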
